A study of Drosophila melanogaster and Homo sapiens with 10 samples.

How the data were processed

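Nascent transcription was measured by PRO-seq, a nuclear run-on assay in which engaged RNA polymerases add biotin-labelled nucleotides to the RNA they are making, so that the position and number of transcribing polymerases can be read by sequencing. There were 10 libraries in 4 groups from 2 cell lines: HCT116, a human colon cancer line, and S2, a Drosophila melanogaster line derived from late-stage embryos. Per the labels' protocols, HCT116 cells were electroporated (1530 V, 1 pulse of 1 ms) with an anti-TAF1 antibody, a procedure known as Trim-Away that directs the bound protein to degradation, and were left for 1 h; the control cells received the pulse without antibody. S2 cells were incubated for 2.5 days with 20 to 40 µg of double-stranded RNA against TAF1 or, as control, against the bacterial gene LacI. The run-on used 25 µM unlabelled CTP in place of 0.25 µM.

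The deposited values were raw counts of reads per gene in 1 table per cell line. Per the file headers, the authors counted reads with featureCounts 1.6.2, with the strand setting 1, over the whole span of 1 transcript per gene. The headers gave no option for reads that map to several places or overlap several spans, which the counter then leaves out, and rows that shared their whole span with another row held 0 counts (138 rows in HCT116 and 243 in S2). Repeated genes, such as the Hsp70 copies and the clustered histone genes, are therefore undercounted, and overlapping genes on the same strand are uncertain. The orientation of the reads before counting was not given in the sources used here, and counts were taken as sense. In S2, the 79 tested ribosomal protein genes had a median of 164 CPM per kb, above 97.5% of tested genes, while HCT116 had no named genes for such a check. The genome build was GRCh38 per the submitters' processing notes, which name this human build for the S2 samples too. No fly build was therefore stated, but the S2 spans match the fly gene table described below. The aligner was not given in the sources used here. Each row held 1 count for the whole gene, so reads of the promoter-proximal region and of the gene body were not separated and no pausing ratio was computed.

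There were 19259 rows for HCT116 and 13916 for S2. S2 rows were named through their transcript identifiers with a RefSeq gene table of the Release 6 assembly, which gave a symbol to 13863 rows; 1 row was left out because its gene had another row with a higher mean count. HCT116 rows carried transcript identifiers that the tables used here did not pair with symbols, so human genes are given by identifier and the human gene lists fixed beforehand were not analysed here. Of matched S2 rows, 99.99% lay within 1 base of or inside the reference gene and 99.96% on its chromosome. The S2 coordinates therefore match Release 6. Starts in the S2 table lay 1 base before the reference gene in 80.4% of named rows, so starts are given here with 1 added. For HCT116 the same offset was assumed. Gene lengths are as deposited, 1 base more than the spans so given.

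Counts were analysed in R 4.3.3 within each cell line. Rows were filtered with filterByExpr (minimum count 10), scaled by TMM and compared with edgeR 4.0.16 (quasi-likelihood test, Benjamini-Hochberg adjustment, called at an adjusted p under 0.05); standard errors of log2 fold changes were derived from the fold change and its F statistic. This left 14842 rows tested in HCT116 and 8500 in S2. Fold changes are TAF1-targeted over control. For S2, 19 gene lists were fixed before the data were examined; the 16 with at least 5 tested members were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over lists, and 3 lists of noncoding or mitochondrial genes had 0 members in the table. The length trend of a library was the median log2 CPM (prior count 2) of the longest tested genes minus that of the shortest, with tested genes ranked by length into 5 classes of equal size, compared between groups by an exact two-sided permutation test. The genes named were set by a rule fixed before the data were examined: the targeted gene, the called genes of largest change in each direction with a mean of at least 5 CPM and no overlap between groups, or, where none was called, the 5 of smallest p in each direction given as values, and the member of smallest p of each tested list, or 3 members of a called list. The limits on CPM and overlap were applied to the 5 of smallest p as well, and for HCT116 no more than 2 identifiers in each direction are given. Among these S2 genes, those without a symbol or with a bare CG, CR or LOC number, small RNAs and pseudogenes were left out. The designs and alternatives were also fixed before the data were examined, except those named as added in the closing section. Figures were drawn with matplotlib 3.10.9.

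Total counts ranged from 32094631 to 54823893 in HCT116 and from 4733207 to 8180749 in S2. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. No 2 libraries matched within sampling noise: the smallest chi-square per degree of freedom between any pair was 8.77. The typical coefficient of variation between replicates was 22.2% in HCT116 and 24.1% in S2. The shared replicate numbers paired the S2 libraries: deviations from the group means correlated at 0.82, 0.56 and 0.64 for replicates 1, 2 and 3, and with the replicate number as a block the coefficient of variation fell to 10.6%.

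The test was tried on simulated data, with 200 of the tested genes changed. For HCT116, the share recovered was 1.49% at 1.5-fold, 16.4% at 2-fold and 83.3% at 4-fold, and 11.8% of the calls were false. For S2 it was 5.97%, 26.9% and 75.8% without a block, and 59.7%, 91.0% and 100% with the block, with 6.49% and 4.57% of calls false. Among simulated S2 lists of 30 genes, camera called the 1 list shifted by 0.3 (log2) and 0 of 20 unchanged lists, with and without the block. The simulated genes varied independently of one another. Estimated inter-gene correlations of the real lists without the block ran from -0.15 (histone genes) to 0.87 (ribosomal protein genes). The simulation therefore does not bound false list calls in the real data. Alternatives were other scaling factors, DESeq2 1.42.0, limma-voom, other filters, the replicate block, each library left out, other rows per gene and an estimated inter-gene correlation; the closing section gives their effect.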

Results

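Transcription by engaged polymerases was profiled after treatments that target TAF1, the largest subunit of the general transcription factor TFIID, to ask how TFIID bears on promoter-proximal pausing of RNA polymerase II. The HCT116 experiment compared 2 libraries of cells electroporated with an anti-TAF1 antibody with 2 libraries of cells given the pulse alone. The S2 experiment compared 3 libraries treated with TAF1 double-stranded RNA with 3 treated with LacI double-stranded RNA. Total counts were 50414815 and 47072601 in HCT116 antibody replicates 1 and 2 and 32094631 and 54823893 in control replicates 1 and 2. In S2 they were 7999946, 8180749 and 7564281 after TAF1 double-stranded RNA and 5794012, 4733207 and 5447362 after LacI double-stranded RNA, so each knockdown library was deeper than each control (exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). Because each gene had 1 count over its whole span, the values combine paused and elongating polymerases. The comparisons concern polymerase per gene relative to the other genes of a library. TMM scaling held the median log2 fold change near 0 (0.00374 in HCT116 and 0.00147 in S2), so a change common to most genes could not be seen.

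The HCT116 comparison asked which genes carried more or fewer polymerases 1 h after antibody delivery. Of 14842 genes, 0 were called higher and 0 lower by edgeR (smallest adjusted p = 0.169) and 0 by limma-voom, while DESeq2 called 206 higher and 39 lower. At an unadjusted p under 0.05, 1271 genes were higher and 984 lower, 2255 in all or 15.2% of those tested. That total was 739 without antibody replicate 2, 850 without control replicate 1 and 3421 without control replicate 2. The antibody and control libraries did not overlap in 7347 genes, 49.5% of those tested, against 33.3% by chance for 2 against 2. Many genes varied together, with 65.5% of the variance on the first principal component. Such genes can lift a single split above the chance share, so the excess is no test of the antibody. Among genes of at least 5 CPM whose groups did not overlap, the one higher with the smallest p, NM_021109, on the plus strand of the X chromosome (12975107 to 12977227, GRCh38), measured 149 ± 30.1 CPM in the antibody group and 47.8 ± 6.77 CPM in the control (SD, n = 2), a log2 fold change of 1.64 ± 0.27 (SE; adjusted p = 0.169 by edgeR). NM_138356, on the minus strand of chromosome 15 (45167214 to 45201175), measured 103 ± 5.98 CPM against 39.6 ± 2.77 CPM (SD, n = 2), a log2 fold change of 1.38 ± 0.25 (SE). In the other direction, NM_012284, on chromosome 12 (49539157 to 49558312), measured 70.6 ± 7.29 CPM with antibody and 200.2 ± 113 CPM without (log2 fold change -1.50 ± 0.35, and -0.78 without control replicate 1). NM_018226, on chromosome 2 (240568587 to 240578732), measured 16.4 ± 2.74 CPM with antibody and 59.7 and 30.2 CPM in control replicates 1 and 2 (log2 fold change -1.46 ± 0.35, and -0.90 without control replicate 1). The identifiers were not named here, so the row of TAF1 itself and the human gene lists were not analysed here.

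The count of called HCT116 genes depended on the method and on single libraries. Without the filter on low counts edgeR called 274 genes higher and 78 lower, of which 187 and 34 were also among the DESeq2 calls. The shared genes, compared after the data were seen, had median lengths of 15757 bases (higher) and 18602.5 bases (lower), and the tested genes one of 27740. Without antibody replicate 1, without antibody replicate 2 and without control replicate 2, edgeR called 524, 5 and 38 genes higher and 165, 0 and 76 lower, and without control replicate 1 it called 0 in either direction.

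The balance of long and short genes was compared because whole-gene reads mix the promoter-proximal region with the gene body. In HCT116 the median log2 CPM of the longest genes (84269 bases or more, 2968 genes) exceeded that of the shortest (up to 8636 bases) by 1.86 ± 0.03 with antibody and by 1.89 ± 0.28 in the control (SD, n = 2), a difference of -0.03 (exact two-sided permutation p = 1.0, where 0.333 is the smallest that 2 against 2 allows). The control libraries lay on either side of both antibody libraries, at 1.69 and 2.09. The difference was -0.23 without control replicate 1 and 0.17 without control replicate 2.

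**Figure D1:**
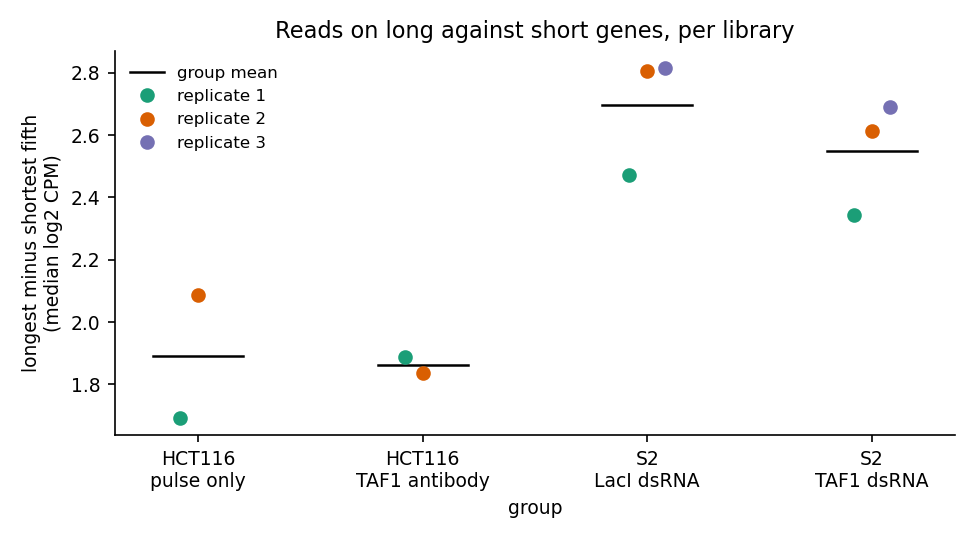
Median log2 CPM of the longest of 5 length classes of tested genes minus that of the shortest, per library (points, coloured by replicate number) with group means (bars). The 2 HCT116 antibody libraries lie between their controls, and S2 replicate 1 lies lowest in both S2 groups, at 2.47 and 2.34.

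Taf1, the gene targeted by the RNA interference, lies on chromosome 3R (6646889 to 6656048, plus strand, in the coordinates of the fly gene table). In S2 cells, its transcription was not lower in the knockdown. It measured 141 ± 2.61 CPM after TAF1 double-stranded RNA and 125 ± 17.5 CPM in the control (SD, n = 3), a log2 fold change of 0.17 ± 0.15 (SE; adjusted p = 0.9996 by edgeR), and one of 0.06 without control replicate 1. Control replicates 1, 2 and 3 measured 105, 132 and 138 CPM and the knockdown replicates 140, 143 and 138 CPM. RNA interference acts on mature RNA and PRO-seq measures RNA being made, so the value does not check the knockdown or the labels.

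The S2 comparison asked which genes carried more or fewer polymerases after 2.5 days with TAF1 double-stranded RNA. Of 8500 genes, 0 were called higher and 0 lower by edgeR (smallest adjusted p = 0.9996), and 0 by DESeq2 or limma-voom. At an unadjusted p under 0.05, 30 were higher and 52 lower (82 in all, or 0.965% of those tested). The total was 127, 155 and 31 without control replicates 1, 2 and 3. A share of 0.965% is below what that threshold gives by chance. The unblocked test counts differences between the pairs as spread, so its p-values are not calibrated here. The groups did not overlap in 463 genes, 5.45% of those tested, against 10% by chance for 3 against 3 unpaired libraries. Replicate numbers paired these libraries, so the 10% does not apply as a chance share and the lower value has no reading. The genes named next had a gene name, at least 5 CPM and groups that did not overlap. Among such genes they had the smallest p in each direction. Without overlap, all same-numbered pairs go the same way, so that is no further observation. These genes are given as values, with SEs on the log2 fold change and n = 3 per group. Among those higher in all 3 same-numbered pairs, tun measured 314 ± 24.7 CPM against 217 ± 9.27 CPM in the control (log2 fold change 0.53 ± 0.14). Sap30, a subunit of the Sin3 histone deacetylase complex, measured 56.6 ± 0.935 CPM against 40.6 ± 2.75 CPM (0.48 ± 0.14 in log2). Coa7, a cytochrome c oxidase assembly factor, Dlc90F, a dynein light chain, and pnut, a septin, had log2 fold changes of 0.40 ± 0.13, 0.40 ± 0.14 and 0.35 ± 0.12.

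Among the genes lower in all 3 pairs, He, a surface protein of blood cells, measured 67.5 ± 18.1 CPM after TAF1 double-stranded RNA and 105 ± 3.19 CPM in the control (log2 fold change -0.64 ± 0.21). IscU, the scaffold for iron-sulfur cluster assembly, measured 94.6 ± 3.28 CPM and 132 ± 3.64 CPM (-0.48 ± 0.12 in log2). rho-4, a rhomboid protease, ZnT77C, a zinc transporter, and Fur2, a furin protease, had log2 fold changes of -0.59 ± 0.17, -0.50 ± 0.16 and -0.47 ± 0.15. With the replicate number as a block, edgeR still called 0 genes (smallest adjusted p = 0.382), while 417 genes were higher and 493 lower at an unadjusted p under 0.05. DESeq2 with the block, added after the data were seen, called 1 gene higher and 10 lower (limma-voom with the block, also added, called 0), with tun, rho-4 and sr, an Egr-family transcription factor, among them.

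**Figure D2:**
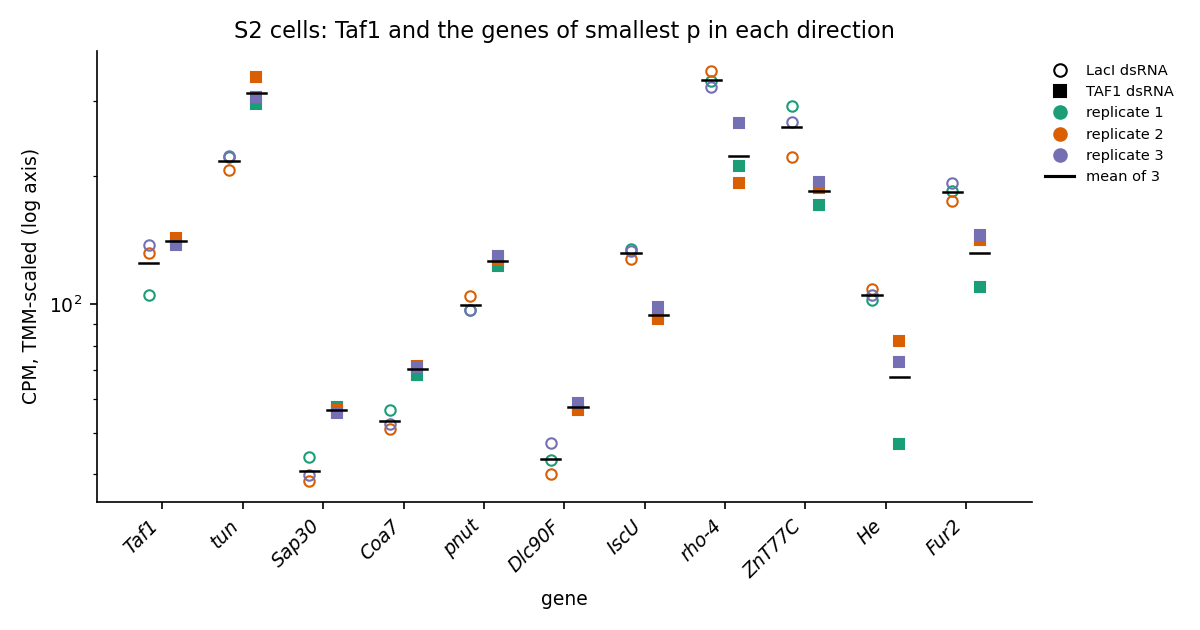
TMM-scaled CPM per S2 library (log axis) for Taf1 and the genes of smallest p in each direction, with circles for LacI and squares for TAF1 double-stranded RNA, colours for replicate numbers and bars for means of 3. Taf1 control replicate 1, at 105 CPM, lies below the other 5 libraries, and the groups of each of the other 10 genes do not overlap.

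Genes of the transcription machinery gave no list call in S2 in the unblocked fit of all libraries. Of 17 tested genes of the TFIID list, 10 had a fold change above 0 and 7 below, with a median log2 fold change of 0.07 (camera adjusted p = 0.262). Besides TFIID subunits, the list as fixed holds the related genes Trf, Trf2, nht, can, sa and mia. Taf7 measured 46.2 ± 5.18 CPM against 35.3 ± 3.66 CPM in the control (SD, n = 3). The 42 genes of general transcription factors and Mediator had a median of 0.04 and the 27 genes of pausing and elongation factors one of 0.04 (camera adjusted p = 0.308 for both). With 1 library left out, these medians ranged from 0.04 to 0.08 for TFIID, 0.01 to 0.06 for general factors and 0.03 to 0.08 for pausing factors. In these lists Mat1, a subunit of the kinase module of TFIIH, had a log2 fold change of 0.43 ± 0.18 and Atu, a subunit of the Paf1 complex, one of 0.21 ± 0.12 (SE). In each of the 16 lists, 0 members were called by edgeR over all genes and 0 when adjusted over the list alone. With TMM scaling and no block, camera called 0 lists with all libraries, but 4, 3 and 3 lower without control replicate 1, knockdown replicate 2 and knockdown replicate 3. It called 1, 2 and 4 higher without control replicate 2, control replicate 3 and knockdown replicate 1.

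Blood cell genes gave a list call in S2 that depended on the fit. The 27 tested hemocyte markers, genes of the blood cells that S2 cells resemble, had a median log2 fold change of -0.13, with 20 members below 0, and were not called without the block (camera adjusted p = 0.0911). With the replicate block the hemocyte list was called lower (median -0.17, 21 of 27 below 0, camera adjusted p = 0.00316). It was not called with an estimated correlation (camera adjusted p = 0.529) or without both libraries numbered 1 (median -0.11, camera adjusted p = 0.234). Both of those fits leave few degrees of freedom, so they cannot decide whether the call holds. Markers of other cell types lay below 0 in the blocked fit as well, in 8 of 9 ovary and germline genes (median -0.13) and 8 of 10 neuron and muscle genes (median -0.07), and were not called (camera adjusted p of 0.125 and 0.306). The hemocyte members of smallest blocked p, chosen after the values were seen, were He, Pvr, a receptor tyrosine kinase, and Tig, an extracellular matrix protein, with blocked log2 fold changes of -0.68 ± 0.14, -0.33 ± 0.10 and -0.37 ± 0.13 (SE). Adjusted over the list alone, 1 of the 27, and 1 of the 10 neuron and muscle genes, passed as lower in edgeR with the block. Without knockdown replicate 1 the unblocked hemocyte median was 0.00899, and the list was called lower without control replicate 1 and without knockdown replicates 2 and 3 (medians of -0.27 in each). The 41 cell cycle and DNA replication genes followed the same course, with a median of -0.07 and camera adjusted p = 0.155 without the block. With the block, their median was -0.09, 34 of 41 lay below 0 and camera adjusted p was 0.0173, but adjusted p was 0.529 with an estimated correlation and 0.356 without both libraries numbered 1. Pair 2 went the other way for the cell cycle list (median 0.06, against -0.22 and -0.11 in pairs 1 and 3). Its member fzy, the fly Cdc20, had a log2 fold change of -0.25 ± 0.20 (SE). Without the block, the cell cycle list was called higher without knockdown replicate 1 (median 0.12) and lower without control replicate 1 (-0.18) and without knockdown replicate 2 (-0.25). Its median was 0.06, not called, without control replicate 2.

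Stress, signalling and immune genes gave no list call in S2 in the unblocked fit of all libraries with TMM scaling. Median log2 fold changes were -0.01 for 23 immediate early and JNK/AP-1 genes (0.05 when scaled by library size alone), 0.05 for 17 heat shock genes, 0.03 for 24 IMD and Toll immune genes, 0.04 for 28 unfolded protein and oxidative stress genes and -0.07 for 20 ecdysone response genes (camera adjusted p from 0.239 to 0.431). The mean of the immediate early list was -0.11, and its member sr measured 303 ± 72.0 CPM against 451 ± 84.3 CPM in the control (SD, n = 3). Calls of 3 of these lists changed when a single library was left out, which also unbalanced the replicate numbers between the groups. Heat shock and unfolded protein and oxidative stress genes were called higher without control replicate 3 (medians 0.24 and 0.15) and without knockdown replicate 1 (0.19 and 0.14). Without control replicate 1 their medians were -0.10 and -0.02, not called. Immediate early genes were called lower without control replicate 1 (-0.13) and without knockdown replicate 3 (-0.18). Adjusted over the list alone in the blocked edgeR fit, 3 immediate early genes and 1 ecdysone response gene were lower. Hsp26 had a log2 fold change of 0.28 ± 0.21, PGRP-SD, which recognises peptidoglycan, 0.61 ± 0.28, Gclm, a subunit of the enzyme that starts glutathione synthesis, 0.23 ± 0.17, and hid, which promotes apoptosis, -0.45 ± 0.28 (SE).

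Housekeeping and RNA interference genes gave no list call in that fit either. Medians were -0.06 for 79 ribosomal protein genes, -0.04 for 14 glycolysis genes (0.00314 and 0.03 when scaled by library size alone) and -0.07 for 19 RNA interference genes (camera adjusted p of 0.308, 0.457 and 0.262). With 1 library left out, the RNA interference median ranged from -0.10 to -0.02. Ribosomal protein genes were called lower without control replicate 1 (median -0.27), knockdown replicate 2 (-0.17) and knockdown replicate 3 (-0.19), and higher without control replicate 2 (0.14) and knockdown replicate 1 (0.16). RpS26 and Pglym78, a phosphoglycerate mutase, had log2 fold changes of 0.27 ± 0.20 and 0.36 ± 0.20, and Hen1, which methylates small RNAs, one of -0.27 ± 0.12 (SE). Of 115 histone genes listed, 6 were tested, with a median of 0.04 and a camera direction below 0 (adjusted p = 0.771). The named member, His4r, is replication-independent (log2 fold change -0.30 ± 0.20, SE). Markers of other cell types had medians of -0.09 for 10 neuron and muscle genes and -0.11 for 9 ovary and germline genes (camera adjusted p of 0.771 and 0.155). With 1 library left out, these ranged from -0.20 to -0.00243 and from -0.14 to -0.05. Their members brp, of the synaptic active zone, and tai, a steroid receptor coactivator, had log2 fold changes of 0.65 ± 0.59 and -0.29 ± 0.20 (SE). That of brp was 0.13 without knockdown replicate 1 and 1.24 without control replicate 1.

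**Figure D3:**
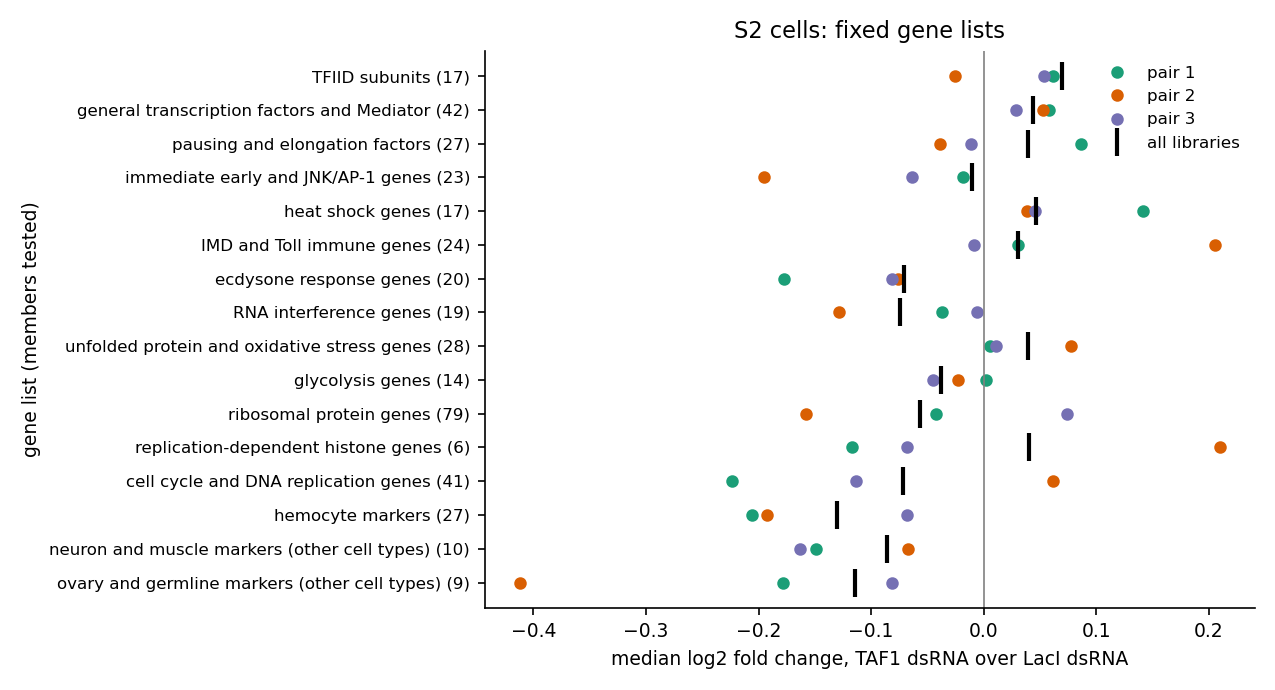
Median log2 fold change of each fixed gene list in S2 cells (members tested in brackets), for each same-numbered pair of libraries (points) and from the fit of all libraries (ticks). Hemocyte markers lie below 0 in all 3 pairs, while cell cycle and ribosomal protein genes go both ways.

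Long S2 genes had a lower median relative to short genes in the knockdown library of each same-numbered pair, in a design too small to pass a test. The longest genes (7425 bases or more, 1700 genes) exceeded the shortest (up to 1301 bases) by 2.55 ± 0.18 in median log2 CPM after TAF1 double-stranded RNA and by 2.70 ± 0.20 in the control (SD, n = 3), a difference of -0.15 (exact two-sided permutation p = 0.5, where 0.1 is the smallest possible). Within same-numbered pairs the difference was -0.13, -0.19 and -0.13, a mean of -0.15 with an SD of 0.04 over pairs. The exact two-sided sign-flip permutation p over pairs, added after the data were seen, was 0.25, the smallest that 3 pairs allow. The median log2 difference of the longest genes was -0.08, -0.11 and -0.07 in pairs 1, 2 and 3, and that of the shortest 0.02, 0.07 and 0.05. Leaving out 1 library gave group differences from -0.26 (without control replicate 1) to -0.05 (without knockdown replicate 1).

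**Figure D4:**
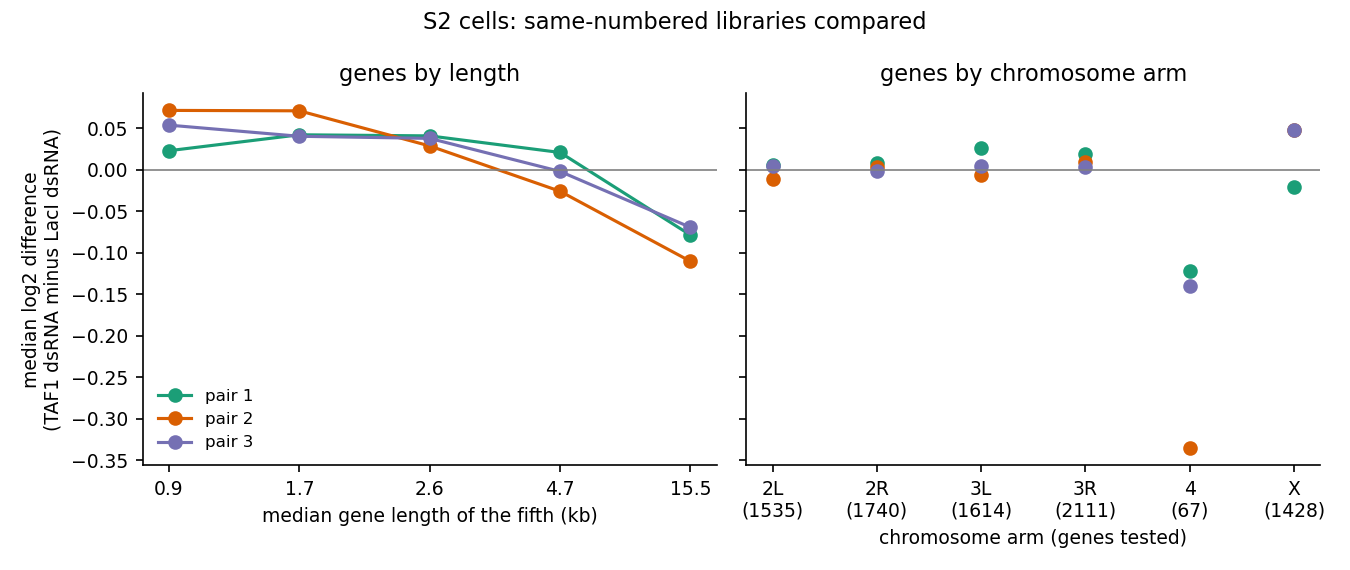
Median log2 difference between the TAF1 and LacI double-stranded RNA libraries of the same number in S2 cells, for 5 length classes of genes (left) and by chromosome arm (right, genes tested in brackets). The longest genes lie below 0 in all 3 pairs, and chromosome 4, at -0.12, -0.34 and -0.14, lies lowest of the arms in each pair.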

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

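Of the tests in this part, the one on a single library was chosen after its result was seen. Rows outside the HCT116 tests, those with too few counts, took a larger share of counts in the antibody libraries than in the controls. The share was 0.0150% (exact Clopper-Pearson 95% interval 0.0146 to 0.0153) and 0.0205% (0.0201 to 0.0209) in antibody replicates 1 and 2, above 0.0129% (0.0126 to 0.0133) and 0.0135% (0.0132 to 0.0138) in control replicates 1 and 2, with intervals for counting error alone. Because antibody replicate 1 exceeded the higher control by only 1.11 times, and the spread between libraries rests on 2 controls, a rise in antibody replicate 2 alone cannot be told apart from an effect of the antibody, which was not tested otherwise. Read-through from an expressed gene ending within 10 kb upstream may contribute: in antibody replicate 2 the rise was 1.00 times as large in 48 rows with such a neighbour as in 2571 rows without (95% interval from resampled rows 0.683 to 1.41), too wide to decide. Even background was not decided. In antibody replicate 2, added reads per kb were 11.6 times as many in the shortest of 5 length classes as in the longest (95% interval 4.25 to 20.1), beyond the bound fixed beforehand. Antibody replicate 1 went the other way (-0.105 in the shortest and 0.00536 in the longest). The minimum count of the filter equals 0.131 reads per kb in a typical row of the longest class, below the 0.224 added in the shortest. That minimum does not cap the reads of a single library, so it cannot be said to have set this outcome. The rows were chosen by their low counts, however, and the ratio of 11.6 rests on 1 library.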

How the results depend on the processing

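The replicate block with DESeq2 or limma-voom, the block with an estimated correlation, the sign-flip test over pairs and the fits without both S2 libraries numbered 1 were chosen after seeing the data. Alternatives for the HCT116 gene lists, for several rows per gene in HCT116 and for a pausing ratio (at least 20 counts in both regions, either cell line) were not run, because rows carried no symbols or 1 count per gene.

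In HCT116, edgeR called 0 genes in either direction with median-of-ratios factors, library size only, upper-quartile factors and the stricter filter, as did limma-voom. DESeq2 called 206 higher and 39 lower, and edgeR without the filter 274 and 78. Replicate numbers did not pair the HCT116 libraries (correlation of deviations -0.07); with the replicate block edgeR called 272 and 78, DESeq2 166 and 28, and limma-voom 197 and 35. The prior degrees of freedom rose from 11.3 to 38.8 without the filter and were infinite with the block in edgeR, whose calls thus rest on a fully pooled spread; the cause was not tested. Leaving out 1 library gave 0 to 524 higher and 0 to 165 lower: 524 and 165 without antibody replicate 1, 5 and 0 without antibody replicate 2, 38 and 76 without control replicate 2, and 0 and 0 without control replicate 1, with the lone sample of a group assumed to vary like the other group. At an unadjusted p under 0.05 these fits had 2525, 739, 3421 and 850 genes. The 4 identifiers named kept their direction in all 56 values, and 27 of these passed the test. The HCT116 length difference ranged from -0.23 without control replicate 1 to 0.17 without control replicate 2, and kept its sign with 3 length classes and with library size only.

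In S2, edgeR called 0 genes under each scaling, filter, choice of rows per gene and library left out, and with the replicate block; limma-voom and DESeq2 also called 0. With the block, DESeq2 called 1 higher and 10 lower and limma-voom 0. The 26 genes named kept their direction in all 494 values, of which 3 passed the test (tun, rho-4 and sr). With 1 library left out, 9 of the 26 moved by over 1.5 times, namely Taf1 and, with log2 ranges, Hsp26 (0.12 to 0.42), PGRP-SD (0.46 to 0.94), hid (-0.66 to -0.25), Pglym78 (0.17 to 0.48), RpS26 (0.14 to 0.45), His4r (-0.46 to -0.20), fzy (-0.42 to -0.10) and brp (0.13 to 1.24). The length difference stayed below 0 in all 9 alternatives.

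Camera called 1 S2 list lower with library size only (hemocyte markers, median -0.08) and 2 lower with the replicate block (hemocyte markers and cell cycle genes), which changed no other call. Both blocked calls were lost with an estimated correlation and without both libraries numbered 1 (0 lists called in each). Leaving out 1 library gave 0 to 4 lists higher and 0 to 4 lower. Of 240 list medians, 193 kept their sign and were not called, 17 kept it and were called, and 30 changed sign; the cause was not tested. Of those 30, 3 were called higher: ribosomal protein genes without control replicate 2, and they and cell cycle genes without knockdown replicate 1. With library size only the signs changed for immediate early (0.047), glycolysis (0.029) and ribosomal protein genes (0.00314). IMD and Toll genes changed sign without the filter (-0.044) and with the stricter filter (-0.016), as did histone genes with the stricter filter (-0.052), and pausing factors without both libraries numbered 1 (-0.00831). With 1 library left out, medians ranged from -0.18 to 0.016 for immediate early, -0.10 to 0.24 for heat shock, -0.026 to 0.18 for IMD and Toll, -0.18 to 0.025 for ecdysone response, -0.053 to 0.15 for unfolded protein and oxidative stress, -0.15 to 0.090 for glycolysis, -0.27 to 0.16 for ribosomal protein, -0.11 to 0.13 for histone, -0.25 to 0.12 for cell cycle and -0.27 to 0.00899 for hemocyte genes. The S2 simulation gave back 5.97% of 1.5-fold changes without the block and 59.7% with it, so small changes may be missed.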

Other observations

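Of the tests in this part, those on the spread between replicates, on a single pair and on level as the whole cause were chosen after their results were seen. Genes of chromosome 4, the small and largely heterochromatic chromosome of the fly, had a median log2 fold change of -0.20 with the replicate block after TAF1 double-stranded RNA: 62 of its 67 tested genes (92.5%) lay below 0, against 45.7% to 50.3% on the other arms, but 0 of the 67 were called by edgeR, DESeq2 or limma-voom, with or without the block (23 lower and 0 higher at an unadjusted p under 0.05 by blocked edgeR, 3 lower unblocked). The tables argue against their length and level as the whole cause, since 0 of 10000 random lists of other genes matched on both (0%, where 0.01% is the smallest share above 0) had a median as low and the lowest reached -0.14. The medians went against a single pair as the source, at -0.12, -0.34 and -0.14 with 49, 64 and 56 of the 67 genes below 0, but do not exclude it: the pair nearest to 0 lay at -5.64 standard errors, which come from resampled genes and hold no spread between libraries. The spread between replicates cannot be told apart from the knockdown: 1 of 4 splits parting all pairs, the real one, lay as far from 0 (highest other 0.13), too few for a share under 0.05. An effect of the TAF1 double-stranded RNA on chromosome 4 may be at work, as a hypothesis found and tested on the same data; DNA copy number was not tested.

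Long S2 genes had lower values in each pair, and fewer polymerases far into them may be a candidate explanation, which whole-gene counts did not test. Counting depth by itself does not account for it: with all libraries thinned to the total of the smallest, the difference kept at least 0.882 of its size in each of 20 draws. Thinning keeps the expected share of each gene, so other differences between libraries that go with depth were not tested. The values go against the whole-gene level of long genes as the whole cause in pairs 2 and 3. There the mean over 5 bins of level lay at -7.73 and -9.79 standard errors from resampled genes, and 9 of 10 bins at -2.76 to -9.82 (the other at -1.20). These standard errors hold no spread between libraries, and genes were not matched on counts per kb, so level is not excluded. In pair 1 the mean of -0.04 lay at -2.53 standard errors, also further than 2 from 0, but level may account for part of that pair: 14 of all 15 bin values lay below 0, yet the bound fixed beforehand counted signs alone, and 3 bins of pair 1 lay near 0 (0.03, -0.01 and -0.00498). The spread between replicates cannot be told apart from the knockdown, with 1 of 4 splits parting all pairs as large and 0.06 the highest other.

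Other splits of the S2 libraries were too few for a share under 0.05, 10 in all and 4 that part every pair. The real split called 0 genes, the highest other 0, and all 10 were as large; it called 0 lists, the highest other 5, and all 10 were as large. With the block, 910 genes had an unadjusted p under 0.05 in the real split and 902 in the highest other (1 of 4 as large), and 2 lists were called in the real split and 2 in the highest other (3 of 4 as large). The split that exchanged the replicate 2 libraries called 127 genes with the block, against 0 in the real split, which points to a structure of the samples that was not tested. Splits without the block that kept both replicate 1 libraries together had up to 1711 genes at an unadjusted p under 0.05, against 82 in the real split, which points to a structure by replicate.

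The HCT116 libraries did not order by group alone. Antibody replicate 1 and control replicate 2 correlated most (r = 0.991 across genes, against 0.981 and 0.978 within the groups). At an unadjusted p under 0.05, the real split had 2255 genes and the 2 other splits 162 and 662. The lowest of 5 level classes of tested genes had a median log2 fold change of 0.28, with antibody replicate 2 0.28 above the mean of all libraries and antibody replicate 1 0.01 above.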
